A study of Mus musculus with 2 samples.

How the data were processed

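In situ Hi-C, which crosslinks chromatin, cuts it and joins DNA ends that lie close together in the nucleus, was made from mature olfactory sensory neurons of adult mice. Per the labels' protocols, the cells were sorted by FACS from the olfactory epithelium of OMP-GFP mice, which mark mature neurons through the olfactory marker protein gene. The labels name the strain 129P2/OlaHsd and mixed sex. There were 2 biological replicates in 1 group, made from 3000000 and 1500000 cells. Per the labels, chromatin was fixed in 1% formaldehyde, cut with DpnII (recognition sequence GATC), filled in with a biotinylated nucleotide and sheared by sonication.

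Per the series design text, the authors pooled both replicates into 1 contact matrix on GRCm38 and called boundaries on it. The boundary caller, its version, its window and the read mapper are not given in the sources used here. The deposited list holds 5 kb intervals, a class (Strong or Weak) and the authors' boundary strength, a score without a stated scale. From the values, Weak covered scores from 0.2 to 0.5 and Strong those over 0.5. The list belongs to the pooled map, so no value has a spread between replicates and no replicate was left out in turn. Contact depth is unknown here, because contact lists, matrices, insulation tracks and compartment tracks were not used here. Every strength printed is the authors' value and serves only to rank or divide boundaries within this list.

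Sequence came from the GRCm38.p6 reference and gene positions from GENCODE mouse release 21, both of the build the list uses. The genome was divided into 5 kb bins on chromosomes 1 to 19 and X. Bins without undetermined bases were called callable and covered 2557 Mb. Of the boundaries, 6 lay in bins with undetermined bases and were left out of tests on callable bins. A feature lay within 20 kb of a boundary when their bins were at most 20 kb apart. The transcription start site (TSS) was the 5′ end of the gene record, and protein-coding genes numbered 21755.

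Observed overlaps were set against 100000 circular shifts within each chromosome, a 2-sided permutation test, for which 2e-05 is the smallest p they can give. Intervals of ratios (95%) came from 10000 resamplings of chromosomes. Differences between Strong and Weak were tested with 100000 permutations of the class within chromosomes. Chromosome-level differences were tested with exact sign flips over chromosomes, 2-sided. For chromosome X, an exact permutation asked which chromosome deviated as far from the mean of the others, and 0.05 is the smallest p this can give, so it cannot pass 0.05. Base composition used 1000 shifts over the boundary bin and its neighbours, 25 kb in all. CTCF sites were exact matches to the core consensus CCASYAGRKGGCRS on either strand. The reversed consensus was the control, and a rotated consensus was added after the reversed one proved rare. The rotated consensus holds the parts of the core in swapped order, so it still shares sequence with the core. An olfactory receptor (OR) cluster was a run of at least 3 OR genes with gaps of at most 1 Mb.

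Lists of genes, 23 in all, were fixed before the data were examined, and their p-values were adjusted by Benjamini-Hochberg over the 23 lists. Of these, 9 were written out gene by gene and the others were symbol patterns. Patterns took pseudogenes as well, so of the 1407 members of the OR list 1135 were protein-coding. The histone pattern works on symbols and can also take genes that are no histone genes, H13 among them. Rplp0 stands in both the housekeeping and the ribosomal protein list. Genes named in the text followed a rule fixed at the same time. It took the gene with the nearest coding TSS within 20 kb of each of the 20 strongest boundaries, up to 3 members per written list with the strongest boundary within 20 kb, and the 5 OR clusters with most genes. Other genes are marked where they appear. P-values describe where boundaries lie in this pooled map, since boundaries, genes and chromosomes are not biological replicates.

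Alternatives were the stronger class or the top 25% of strengths only, other windows, local placement (each boundary moved by 100 to 500 kb, 1000 draws, smallest p 0.002), autosomes only, other cluster definitions and other motif rules. The procedures were tested on simulated data. With boundaries placed at random, 1.5% of 200 runs gave p under 0.05 for TSSs at boundaries, and 0 of 20 runs called a gene list. A planted TSS ratio of 1.56 was recovered as 1.54 over 7972 boundaries. With 40% of the ribosomal protein genes given a boundary, that list was called and 0 others. A planted 60% share of CTCF sites pointing away was recovered as 60.2%. Other planted effects were recovered less closely: an X density ratio of 0.6 as 0.665, a correlation of neighbouring strengths of 0.3 as 0.265 and a proximal minus distal difference of 0.8 per Mb as 0.758. With boundaries planted at OR cluster edges, the share of edges with one was 69.2% where 72.3% was planted. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.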

Results

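The data describe chromatin boundaries, the borders between neighbouring contact domains, in mature olfactory sensory neurons (OSNs), the cells that each express a single OR gene and send an axon to the olfactory bulb. A single boundary list from the pooled map of 2 replicates of 1 group was analysed, so the comparisons are between regions, genes and boundary classes within this map. The list held 8058 boundaries on chromosomes 1 to 19 and X, of which 4092 were Strong (50.8%, 95% exact Clopper-Pearson interval 49.7 to 51.9%) and 3966 Weak. This interval covers the counting of boundaries only. Boundary strength, in the authors' score, ran from 0.2 to 4.32 with a median of 0.509. Adjacent boundaries lay a median of 260 kb apart (interquartile range 180 to 380 kb), and Strong boundaries a median of 400 kb. Spacings with over 50 kb of undetermined bases, 41 among all boundaries, were left out of these medians.

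The strongest boundary, with a strength of 4.32, lay on chromosome 12 at 115830001 to 115835000 in the immunoglobulin heavy chain variable region, over Ighv1-75. The next, with a strength of 4.13, lay on chromosome 1 at 88305001 to 88310000 and covered an exon and UTR of Trpm8, the cold-sensing ion channel gene. Both were chosen after their values were seen, since no coding TSS lay within 20 kb. Of the 20 strongest boundaries, 13 had a coding TSS within 20 kb and 4 a CTCF core match. The 13 genes were Sfi1, Pdcl, Eif1, AW209491, Trrap, Gm527, Zfp984, Speer4e, Olfr986, Fstl5, Rps23, Selenow and Gm5662. The boundaries at Eif1, a translation initiation factor gene (strength 3.26, chromosome 11 at 100315001 to 100320000), and at Trrap, a histone acetyltransferase cofactor gene (3.22, chromosome 5 at 144765001 to 144770000), lay in the same 5 kb bin as the TSS. The boundary of Olfr986 (3.07, chromosome 9 at 40175001 to 40180000) lay 5 kb from the TSS and that of Rps23 (3.03, chromosome 13 at 90915001 to 90920000) also 5 kb. An assembly gap lay within 50 kb of 1 of these 20 boundaries and of 35 of all 8058 (0.434%). In callable bins, 29 boundaries lay that near a gap against 67.2 expected (ratio 0.432, shift permutation p = 2e-05). The circular shifts treat bins near gaps like all others, which limits their expected values. Whether structural differences between the 129P2/OlaHsd strain and the reference genome affect the strengths of the 20 strongest boundaries was not tested. This holds for those at Ighv1-75, Sfi1, Speer4e and Zfp984 in particular (chosen after their values were seen).

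Chromosome X carried few Strong boundaries. It had 0.865 Strong boundaries per callable Mb against 1.66 ± 0.202 on the autosomes (SD, n = 19 chromosomes), a ratio of 0.521, and it lay below every autosome (range 1.29 to 2.22). Only 31.3% of the boundaries on X were Strong. For all boundaries X had 2.77 per Mb against 3.18 ± 0.209, a ratio of 0.869, inside the autosomal range of 2.71 on chromosome 14 to 3.66 on chromosome 11. The exact permutation over 20 chromosomes gave p = 0.15 for all boundaries and p = 0.05 for Strong ones, the smallest it can give.

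**Figure D1:**
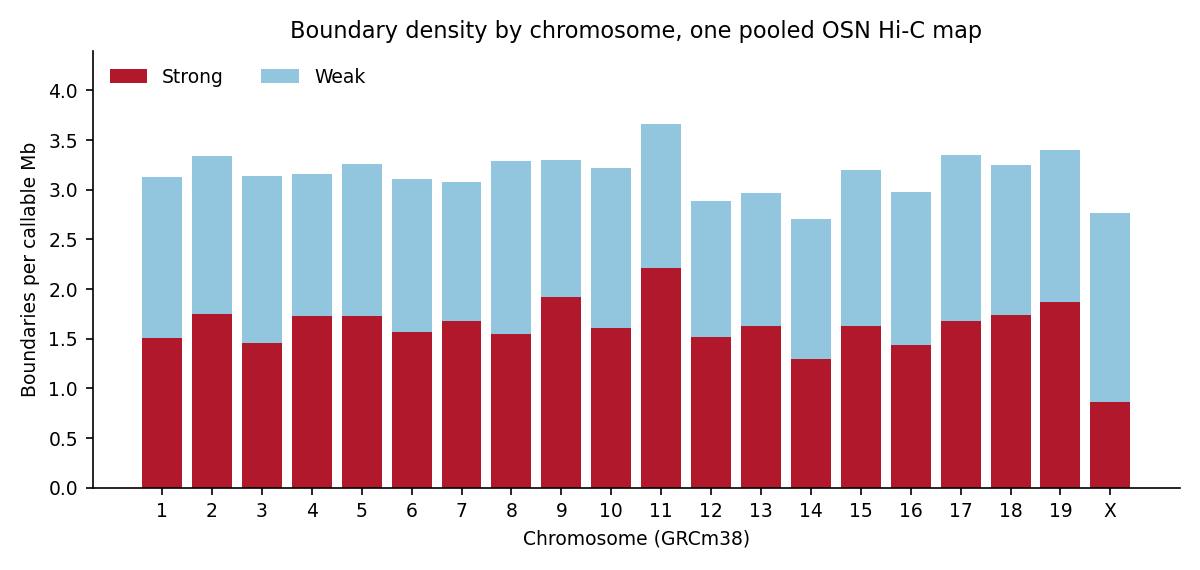
Boundaries per callable Mb (vertical axis) on each mouse chromosome (horizontal axis), with Strong boundaries in red and Weak ones stacked in blue, from the pooled OSN map. Chromosome X has 0.865 Strong boundaries per Mb, below the autosomal minimum of 1.29.

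The centromere-proximal part of each autosome, up to its midpoint, held 3.10 ± 0.241 boundaries per Mb and the distal part 3.26 ± 0.313 (SD, n = 19 autosomes). The proximal minus distal difference was -0.166 ± 0.370 and was above 0 in 7 of 19 autosomes, which did not pass the exact sign-flip test (p = 0.0664). When the middle part of each autosome was left out the difference was -0.270, with p = 0.0152 by the same exact test. The strengths of adjacent boundaries on a chromosome showed no detectable correlation across 8038 pairs (Spearman's rho 0.0104, permutation p = 0.863), and pairs of boundaries are not independent replicates. Within the top 25% of strengths rho turned to -0.189 (permutation p = 2e-05), and for pairs over 200 kb apart it was 0.0464 (permutation p = 0.0111).

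Protein-coding TSSs lay at boundaries more often than shifted places did. A TSS within 20 kb was found at 37.6% of boundaries (3029 of 8052) against 26.4% expected, a ratio of 1.43 (95% interval 1.38 to 1.48, permutation p = 2e-05, the smallest the circular shifts can give). Strong boundaries had one in 47.5% and Weak boundaries in 27.4%, a difference of 20.03 percentage points (95% interval 17.9 to 21.96, permutation p = 2e-05). Against their own shifts the ratio was 1.78 for Strong and 1.06 for Weak boundaries (shift permutation p = 0.0258 for Weak). By decile of strength the share went from 19.4% in the lowest to 52.1% in decile 8 and 49.4% in the highest. Boundaries moved by 100 to 500 kb gave a ratio of 1.27 (permutation p = 0.002, the smallest these draws can give). Whether base composition or nearby CTCF matches account for the share near a TSS was not tested.

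Core matches of CTCF, the zinc finger protein that stalls cohesin at domain borders, lay within 20 kb of 21.9% of boundaries (1763 of 8052) against 10.2% expected. The ratio was 2.14 (95% interval 2.06 to 2.23, shift permutation p = 2e-05). Strong boundaries had a match in 30.3% and Weak boundaries in 13.2%, a difference of 17.1 percentage points (95% interval 15.0 to 18.99, permutation p = 2e-05). With 1 mismatch allowed, which gave 64456 sites in place of 6562, the ratio fell to 1.23 (permutation p = 2e-05). Sites this frequent limit how high a ratio can be. The rotated control consensus without mismatches, chosen after seeing the data, gave a ratio of 1.33 (permutation p = 8e-05), and the reversed consensus gave 16 boundaries against 12.3 expected (p = 0.329). A TSS and a CTCF match were both near 15.0% of Strong and 6.13% of Weak boundaries. Neither was near 37.3% of Strong and 65.5% of Weak boundaries.

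**Figure D2:**
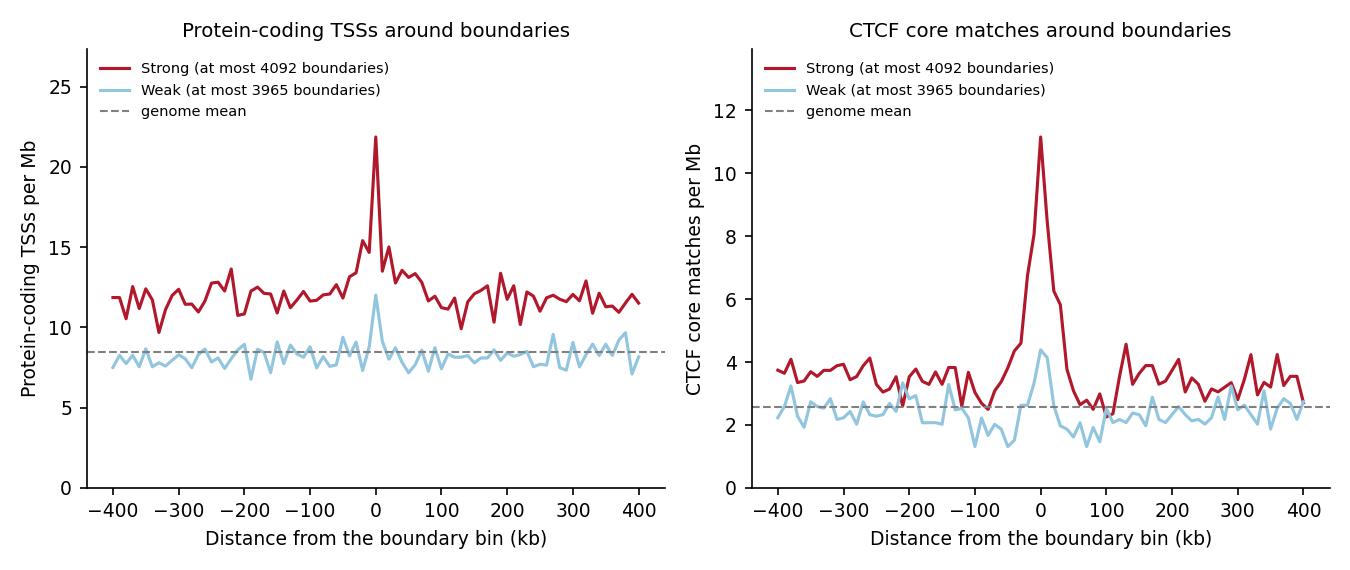
Protein-coding TSSs per Mb (left) and CTCF core matches per Mb (right) in single 5 kb bins taken every 10 kb, by distance from the boundary bin in kb, for Strong (red) and Weak (blue) boundaries, with the genome mean dashed. Both features peak at the boundary bin in either class, and the peaks of Strong boundaries are the higher. TSSs are also denser around Strong than around Weak boundaries 400 kb away.

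CTCF matches near boundaries had a preferred direction. Of the matches within 20 kb of their nearest boundary, 1318 pointed away from it and 653 toward it. The share pointing away was 66.9% (95% interval over chromosomes 65.3 to 68.3%) and was above 50% on 20 of 20 chromosomes, ranging from 55.4 to 71.6% (exact sign-flip p = 1.91e-06). It was 68.1% at Strong boundaries and 63.9% at Weak ones, a difference that was not tested. The rotated consensus pointed away in 57.7% of 112 plus 82 matches, which did not pass the exact test (p = 0.0571). With 1 mismatch allowed in the CTCF core, the share pointing away fell to 57.7% (exact sign-flip p = 1.91e-06).

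**Figure D3:**
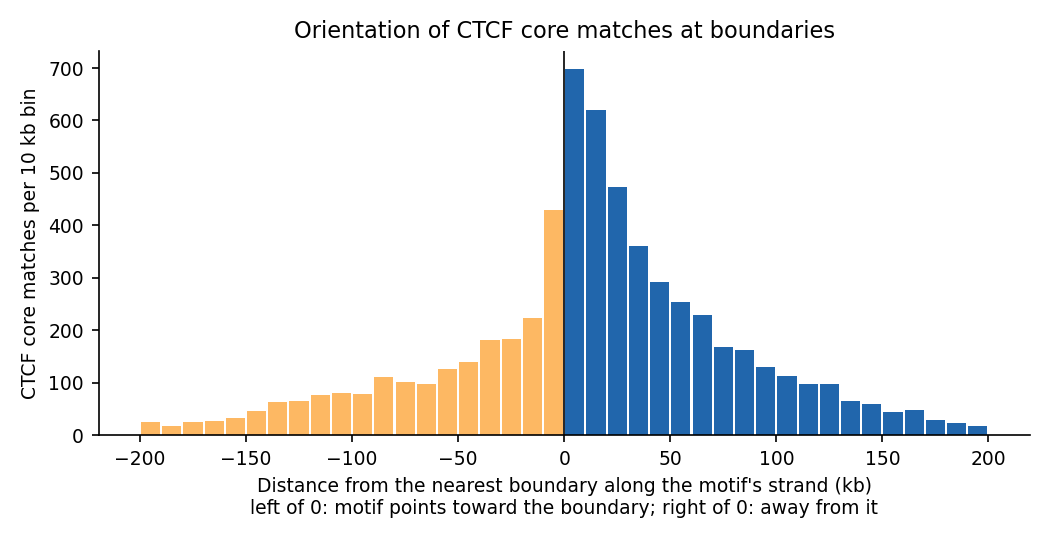
CTCF core matches per 10 kb (vertical axis) by distance from the nearest boundary along the strand of the match in kb (horizontal axis). Matches left of 0 point toward the boundary and matches right of 0 point away from it, and the matches pointing away are the more numerous near 0.

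Boundary surroundings differed in base composition from shifted places. GC content was 42.8% against 41.8% and the soft-masked (repeat) share 35.6% against 34.2%. DpnII sites, where the library was cut, numbered 2.553 against 2.505 per kb (each permutation p = 0.002, the smallest 1000 shifts can give). The difference in GC content was 1.01 percentage points, and 2.11 for Strong boundaries alone and 2.22 in the top 25% of strengths. The difference in soft-masked share was -0.849 points for Strong boundaries alone and 0.0152 in the top 25% (permutation p = 0.971), and the difference in DpnII sites for Strong boundaries was 0.00906 per kb (permutation p = 0.2).

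Ratios of gene lists are against shifted places, where coding genes as a whole had a ratio of 1.479 and 21.2% had a boundary within 20 kb of the TSS. Among genes of OSN function, 5 of 22 (22.7%) had a boundary within 20 kb of the TSS against 3.09 expected, a ratio of 1.62 that did not pass the test (shift permutation p = 0.372, adjusted p = 0.577). Slc17a6, the vesicular glutamate transporter gene (strength 2.68, 20 kb away, chromosome 7 at 51600001 to 51605000), and Gnal, the olfactory G protein subunit gene (2.31, 15 kb away, chromosome 18 at 67100001 to 67105000), lay near Strong boundaries. So did Gng13 (1.03). Regulators of OR choice and nuclear architecture had a boundary at 6 of 25 genes (24.0%, ratio 1.65, adjusted permutation p = 0.549), among them Ebf3 (2.61), Emx2 (2.35) and the histone methyltransferase gene Ehmt1 (0.875). Axon guidance and adhesion genes had one at 7 of 18 against 2.53 expected, a ratio of 2.77 (95% interval 1.248 to 4.06, permutation p = 0.0158, adjusted p = 0.121). Robo2, a Slit receptor gene (1.70, 5 kb away), Ncam2 (1.53, 10 kb away) and Igf1r (1.02, 5 kb away) led that list. It passed with Strong boundaries only (adjusted permutation p = 0.0237), in the top 25% of strengths (0.00736) and within 10 kb (0.0373), and in the other settings the adjusted p was 0.0909 to 0.123. Against other coding genes its share was 38.9% against 21.2%, which did not pass (Fisher's exact p = 0.0809, adjusted p = 0.207).

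Lists of other cell types of the epithelium and of housekeeping genes did not pass adjustment, with adjusted permutation p from 0.213 to 0.946. Immature OSN genes had a boundary at 1 of 14 members (Stmn2, Weak, 0.412) and progenitor genes at 3 of 14 (Tead2 1.02, Insm1 0.380 and Pax6 0.235). Horizontal basal cell genes had a boundary at 0 of 11 members against 1.68 expected. Sustentacular and gland genes had one at 3 of 16 members, each Weak (Sox9 0.497, Fmo2 0.331 and Hes1 0.281). Genes of blood, immune, endothelial and glial cells had one at 6 of 16 members (ratio 2.59, permutation p = 0.0529, adjusted p = 0.213), with the neighbouring complement genes C1qa and C1qb sharing a boundary of strength 0.903 and Pecam1 near one of 0.810. Housekeeping genes had one at 6 of 28 members (21.4%, near the share of coding genes as a whole), led by Snrpd3 (1.67), Eef2 (1.0) and Tubb5 (0.984).

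Cytosolic ribosomal protein genes were the 1 list of 23 that passed adjustment, and 4 lists had an unadjusted p under 0.05. A boundary lay within 20 kb of 42 of 88 members (47.7%) against 12.6 expected, a ratio of 3.33 (95% interval 2.58 to 3.97, shift permutation p = 2e-05, adjusted p = 0.00046). Over the alternatives the adjusted permutation p was at most 0.046, with local placement. There the ratio was 2.96 and the unadjusted permutation p was 0.002, the smallest those draws can give. Of these 42 genes, 29 had a Strong boundary as the nearest. A boundary of either class lay within 5 kb of 24 of the 42, and in the same 5 kb bin as the TSS for 9. After Rps23, the strongest lay near Rps24 (2.74, 5 kb away), Rps15a (2.42, 20 kb away) and Rps3 (2.02, 5 kb away), which were chosen after their values were seen. Fisher's exact test against other protein-coding genes, which ignores the clustering of gene families, called 8 of the 23 lists after adjustment. Of these, ribosomal protein and histone genes had a higher share than other coding genes, and the rest had a lower one.

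Tandem gene families gave no other call. Histone genes had a boundary at 31 of 78 members (ratio 2.90, permutation p = 0.00806, adjusted p = 0.0927) and Hox genes at 11 of 39 (ratio 1.88). OR genes had fewer than shifted places, 167 of 1407 against 205.7 expected, a ratio of 0.812 (95% interval 0.658 to 1.11, permutation p = 0.0399, adjusted p = 0.213). Vomeronasal type 1 receptors had one at 18 of 207 and type 2 receptors at 10 of 121 (ratios 0.626 and 0.579, both adjusted permutation p = 0.213). Clustered protocadherins, the neuronal cell surface genes, had one at 1 of 58 (ratio 0.118, adjusted permutation p = 0.406). The other families lay between ratios of 0.389 and 1.62, with adjusted permutation p of 0.376 or more: keratins 3 of 50, trace amine receptors 1 of 15, Ms4a genes 2 of 19, defensins 9 of 64, zinc finger genes 60 of 417, cytochrome P450 genes 18 of 94 and killer lectin receptors 5 of 22.

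**Figure D4:**
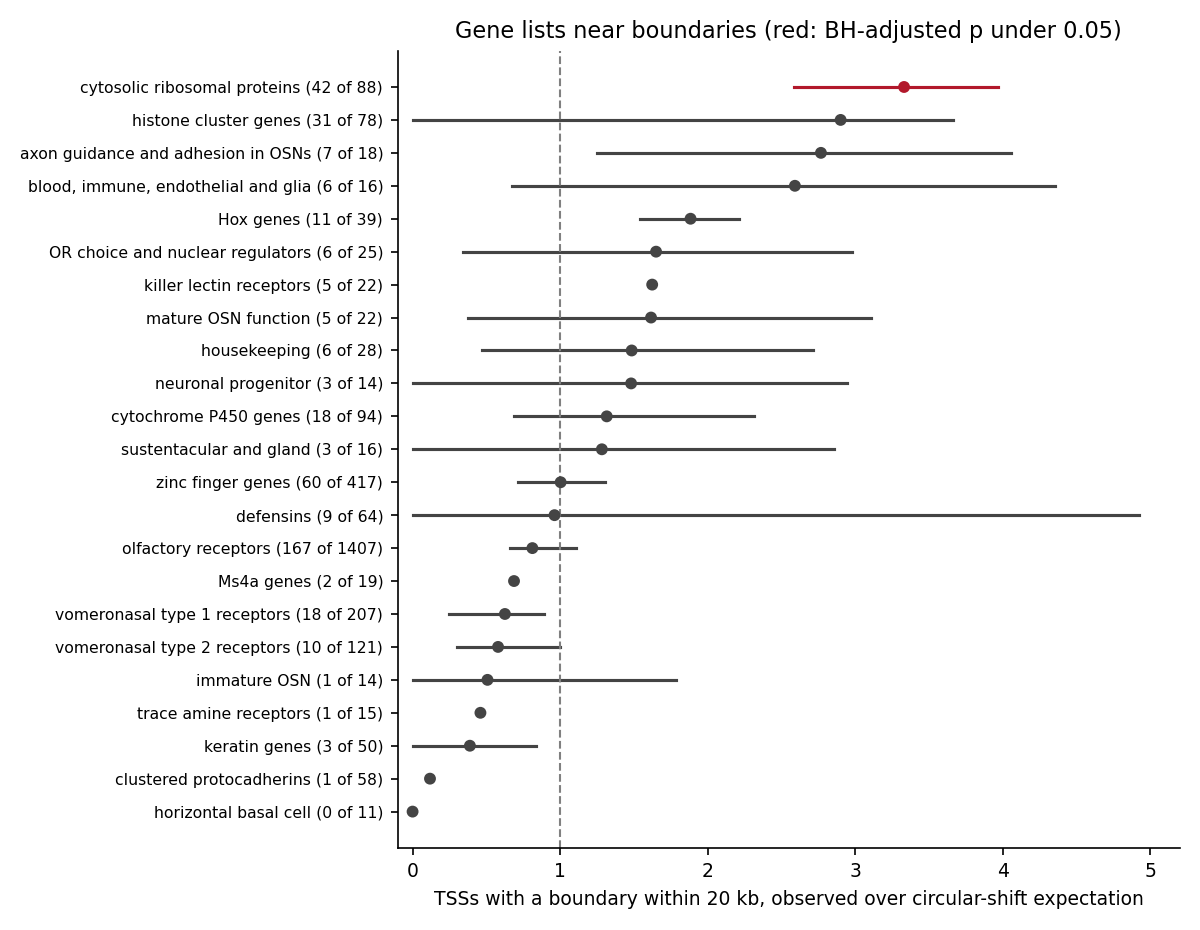
Observed over expected number of member TSSs with a boundary within 20 kb (horizontal axis) for the 23 gene lists (vertical axis, with the number of members that have a boundary). Points are ratios, lines are 95% intervals over chromosomes (a family on 1 chromosome has none), and only the ribosomal protein list, at 3.33, passes adjustment.

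Protein-coding OR genes alone formed 36 clusters with 1115 genes. With pseudogenes included, as used below, OR genes formed 39 clusters with 1380 genes. A boundary lay within 50 kb of 51 of the 78 cluster edges (65.4%) against 33.5% expected, a ratio of 1.95 (95% interval 1.71 to 2.25, shift permutation p = 2e-05). Of the clusters, 14 had a boundary at both edges, 23 at a single edge and 2 at neither. Boundaries at the edges were more often Strong, 40 of 51 (78.4%) against 50.6% of all others, a difference of 27.8 percentage points (95% interval 12.8 to 41.2, permutation p = 0.00026). Another coding TSS lay within 50 kb of 49 of the 78 edges, and Strong boundaries were more often near a TSS in general. Whether this accounts for the difference was not tested. Inside the clusters and over 50 kb from the ends, 26 of 84 boundaries were Strong (31.0%), a difference of -20.04 percentage points from all others (95% interval -32.1 to -6.31, permutation p = 8e-05). The density of boundaries inside did not differ detectably from that outside, at 3.05 and 3.15 per Mb (ratio 0.952, 95% interval 0.768 to 1.20, shift permutation p = 0.547), and the ratio was 0.741 with Strong boundaries only (permutation p = 0.0508) and 1.07 without chromosome 2, the latter chosen after seeing the data.

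The largest cluster, on chromosome 2 from 85330779 to 90403897, held 287 OR genes and 10 boundaries. Its edges lay 45 kb from a boundary of strength 0.5 and 70 kb from a Weak one of 0.394. The cluster on chromosome 7 from 102476579 to 105369355, with 156 genes, began in the bin of a Strong boundary of 2.67 and ended 150 kb from a Weak one. That on chromosome 9 from 37708964 to 40190134, which held the third most OR genes, had Strong boundaries at both edges, of 0.998 at 45 kb and 3.07 at 15 kb. The cluster on chromosome 19 from 11826803 to 13921866 (91 genes) had a Strong boundary of 1.38 at 5 kb from its end and none within 50 kb of its start. The next on chromosome 7, from 106675005 to 108894420 (80 genes), had Strong boundaries at both edges (1.28 at 35 kb and 1.05 at 30 kb).

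**Figure D5:**
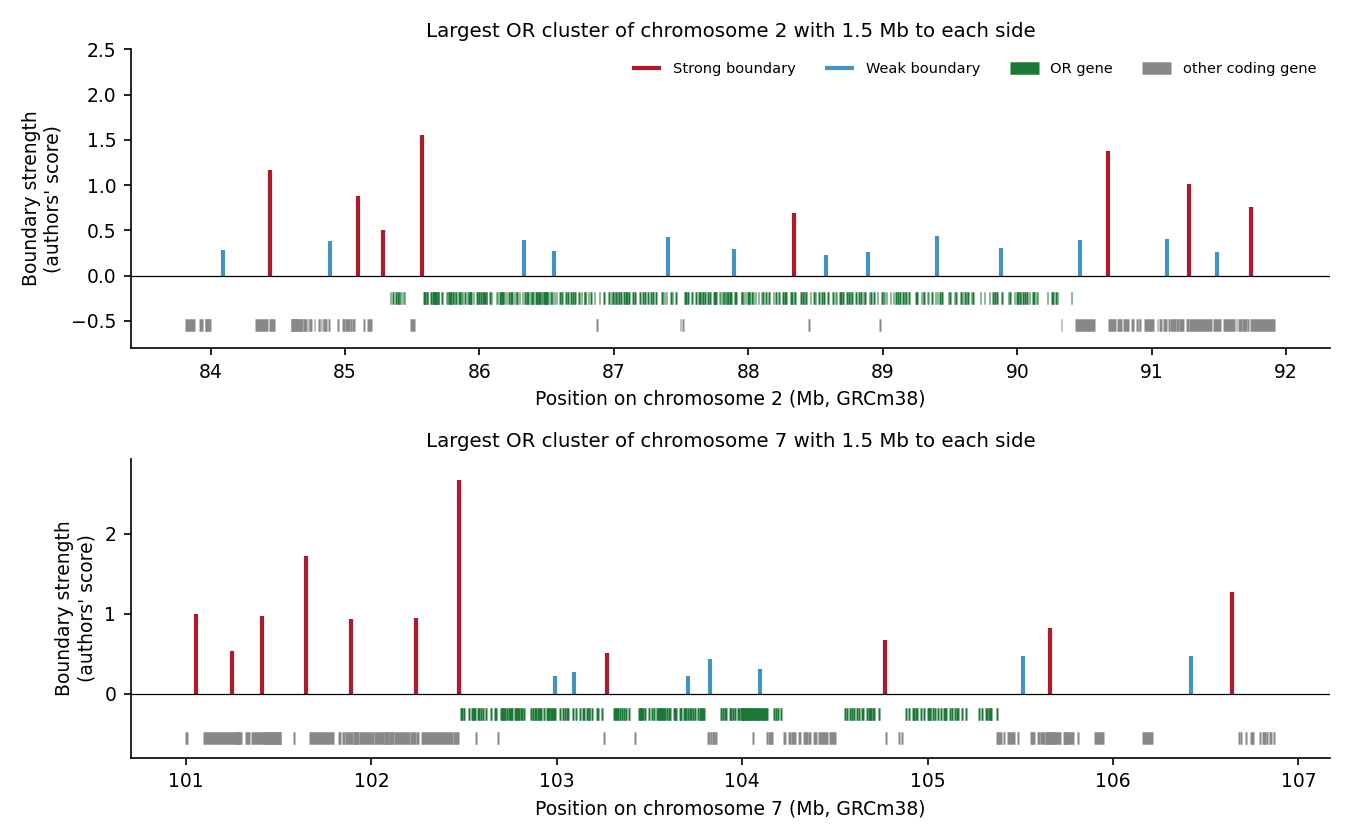
Boundaries (lines, height is the authors' strength score, red Strong and blue Weak) around the largest OR clusters of chromosomes 2 and 7, with the OR genes of these clusters in green and other coding genes in grey below, by position in Mb on GRCm38. The chromosome 7 cluster begins at a Strong boundary of 2.67, and most boundaries among the OR genes are Weak.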

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

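Of 75 alternative values of the tested results and counts, 4 could not change by design: the merging of boundaries within 10 kb, since none lay closer than 45 kb, and 3 for the density of X, whose test cannot pass the threshold. Of the other 71, 56 kept their direction and their side of the threshold or stayed within their limits, among them those for TSSs and CTCF matches at boundaries, CTCF orientation, both class differences and OR cluster edges. The 56 include the rotated consensus, which is a control, so its value does not show that the CTCF result is stable. They also include splits at the median strength of 0.509, which nearly repeat the class limit of 0.5. With 1 mismatch allowed, the CTCF ratio fell from 2.14 to 1.23 and the share pointing away from 66.9 to 57.7%. The rotated consensus without mismatches had a ratio of 1.33 and a share of 57.7%. It had 1120 sites against 64456 for the core with 1 mismatch. Frequent sites limit how high a ratio can be, so these ratios cannot be ranked. Edge ratios ran from 1.34 within 100 kb to 4.15 in the top 25% of strengths. No replicate could be left out, because the list was called on the pooled map, and contact depth, unknown here, limits which weak boundaries could be called. The number of boundaries was 4092 with Strong ones only and 2015 in the top 25% of strengths, by construction. The Strong share was 51.9% on autosomes, and the median spacing 400 kb for Strong boundaries and 280 kb on X, the last chosen after seeing the data. The proximal minus distal difference passed in the top 25% (-0.126, p = 0.0165) and with the middle part of each autosome left out (-0.270), both by the exact test. The correlation of neighbouring strengths was -0.189 in the top 25% and 0.0464 (permutation p = 0.0111) for pairs over 200 kb apart. The cause was not tested. Gene lists called numbered 2 with Strong boundaries, in the top 25% and within 10 kb, where axon guidance genes joined the ribosomal protein genes (ratios 4.71, 7.97 and 4.27). Soft-masked share turned to -0.849 points for Strong boundaries and 0.0152 (permutation p = 0.971) in the top 25%, and the GATC difference fell to 0.00906 per kb (p = 0.2) for Strong ones. The cause was not tested. Among 134 list values whose setting could change the result, 131 kept their side of the threshold. Among 70 distances of named genes 54 stayed within 20 kb, but these genes were picked for a boundary within 20 kb. The settings only removed Weak or less strong boundaries, so this count follows from the choice of genes and is no measure of stability. Alternatives chosen after seeing the data were the rotated consensus, X alone, leaving out chromosome 2 or 7, any annotated transcript start, the settings for ribosomal protein against housekeeping genes, where the difference passed Fisher's exact test in 0 of 4 alternatives, and other tandem families without zinc finger genes. Counting any transcript start, axon guidance genes had a boundary at 10 of 18, ribosomal protein genes at 43 of 88, immature OSN genes at 4 of 14 and horizontal basal cell genes at 3 of 11.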

Other observations

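The values in this and the next paragraph were chosen after seeing the data. Vomeronasal receptor clusters, the pheromone receptor families that are also arranged in tandem, held few boundaries. Type 1 receptor clusters had 1.55 boundaries per Mb inside against 3.16 outside (19 against 37.9 expected, ratio 0.502, shift permutation p = 0.0025, adjusted p = 0.0162 over 13 families). Type 2 receptor clusters had 2.01 per Mb (27 against 42.5, ratio 0.635, permutation p = 0.00202, adjusted p = 0.0162). The difference from OR clusters was not tested, nor was the effect of structural differences between the 129P2/OlaHsd strain and the reference genome in these loci. Callable bins were set only by undetermined bases, so duplicated sequence in which reads cannot be placed stayed in. Its effect on these densities, and on the long stretches below, was not tested, so the low densities cannot be read as a trait of chromatin. Stretches without a boundary were ranked only if they held at most 50 kb of undetermined bases. Of the 10 longest of these stretches, 3 held vomeronasal genes, among them the longest, of 3.92 Mb on chromosome 7 from 19965001 to 23890000 with 60 (soft-masked share 63.5%), and the next, of 3.3 Mb from 6945001 to 10250000 with 24. The other 7 held none, among them stretches of 3.265 and 2.985 Mb on chromosome 12. Of 82 stretches over 1 Mb, 2 (2.44%) lay on X, which held 6.38% of the callable sequence.

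Genes near boundaries tended to point away from them. Of 4158 coding TSSs within 20 kb of a boundary, 55.4% were transcribed away from it (95% interval 54.2 to 56.9%), over 50% on 20 of 20 chromosomes (exact sign-flip p = 1.91e-06). The share was 54.7% at Strong boundaries without a CTCF match within 20 kb. A coding 3′ end lay within 20 kb of 37.6% of boundaries against 25.1% expected (ratio 1.501, permutation p = 2e-05). The bodies of the 230 coding genes of 500 kb or more held 441 boundaries against 620 expected (ratio 0.712, permutation p = 2e-05). Over 7 gene classes, boundaries lay near coding genes at a ratio of 1.479, antisense RNA genes at 1.266 (both adjusted permutation p = 7e-05), snRNA genes at 1.22 (0.00341), lincRNA genes at 1.09 and processed pseudogenes at 1.07 (both 0.0228). The ratios of 1.267 for miRNA genes and 1.186 for snoRNA genes did not pass (adjusted permutation p = 0.0992 and 0.119). Differences between the classes were not tested.

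For the patterns weighed next, the tests of housekeeping genes, of the difference between OR and other family edges and of Weak boundaries on X were chosen after their results had been seen in part, and the other tests before. With 1 cell population, no biological explanation was tested against a second group, and the explanations below were set only against values within this map.

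Boundaries at OR cluster edges may have technical or general sources. Coding promoters close to the edges were not enough. At the 29 edges without another coding TSS within 50 kb the ratio was still 1.69 (16 against 9.47 expected, permutation p = 0.0209). A boundary within 50 kb of such an edge can still lie near a promoter further out, and noncoding promoters were not considered. Promoters in general are thus not excluded. A step in base composition was not enough either, since places outside the clusters with an equal step in GC and soft-masked share had a boundary within 50 kb in 37.8%, below the edges' interval of 56.4 to 74.4%. Edges of the other tandem families were also rich in boundaries, at a ratio of 1.62 (95% interval 1.43 to 1.86) against 1.95 for OR clusters (1.71 to 2.25). The limit set beforehand, an interval below the OR ratio, was met but left out the spread of the OR ratio. The difference was 0.328 (95% interval over chromosomes 0.0563 to 0.618), and 0.194 (-0.217 to 0.579) without the zinc finger genes, which held 66 of the 156 edges. Of 12 families, 4 lay over the OR ratio, with 2 to 16 edges each. An effect of tandem families in general might thus make up the pattern and stays open. Also open is whether other cell types have the same borders, which would need a second map.

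For ribosomal protein genes, dense and GC-rich surroundings were a candidate explanation. Other TSSs matched on neighbouring TSSs and GC had a boundary within 20 kb in 23.5%, below the exact interval of the 84 coding ribosomal protein genes (48.8%, 37.7 to 59.96%). Reads shared with processed copies were argued against by 283 ribosomal protein pseudogenes, whose ratio was 1.08 (95% interval 0.805 to 1.41). Ubiquitous use stays open. A boundary lay near 6 of 27 housekeeping genes (22.2%, Fisher's exact p = 0.024 against the ribosomal protein genes). With Strong boundaries only the shares were 33.3 and 22.2% (exact p = 0.342), in the top 25% of strengths 17.9 and 14.8% (exact p = 1), and within 10 kb 34.5 and 18.5% (exact p = 0.152), ribosomal protein genes first. Within 50 kb they were 67.9 and 48.1% (exact p = 0.0719). A hypothesis is that boundaries form at or near these short, highly transcribed genes, which these data could not test without transcript levels.

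For the few Strong boundaries on X, base composition and gene content were candidate explanations, and neither alone was enough. With bins matched on GC and soft-masked share, X still had 0.713 of the expected Strong boundaries, below the autosomal range of 0.837 to 1.13. Over 50 kb from any coding TSS, X had 0.576 Strong boundaries per Mb, below the autosomal range of 0.656 to 1.20. Nearer to a coding TSS it had 1.33, below the autosomal range of 2.25 to 3.20. Composition and gene content were not tested together, so their joint effect stays open. Fewer copies of X in the mixed-sex pool or a mixture of active and inactive X chromosomes might each lower boundary strength there. Neither was tested, and both stay open. X had 1.90 Weak boundaries per Mb, above the autosomal range of 1.34 to 1.74, which follows from its densities of all and of Strong boundaries and so decides nothing about a lowering of strength.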
